A study of Homo sapiens with 73 samples.

How the data were processed

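Per the labels, Huh7 hepatoma cells were cultured overnight, treated with IFN-α or IFN-β at 500 U/ml or with IFN-λ1, IFN-λ2 or IFN-λ3 at 10 ng/ml, and harvested after 0.5, 1, 2, 4, 6, 12 or 24 h, with duplicates at each time. Total RNA was isolated with a column kit, labelled with biotin and hybridised to Illumina bead arrays by standard protocols at a university core facility. The labels give 73 arrays in 36 groups: 4 untreated arrays (a to d), and arrays a and b of each interferon and time, except IFN-λ3 at 4 h, which has array a alone. Whether the replicates are separate cultures, separate RNA preparations or repeated arrays of 1 preparation is not given in the sources used here, so each p measures the spread between arrays, which may be technical only. All untreated arrays belong to time 0.

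The values used were the deposited log2 signals of 47323 probes, 1 per probe and array, between 6.41 and 14.5. The normalization software, background handling and filters of the authors are not given in the sources used here. The values themselves were checked: the sorted values of the arrays differed by at most 0.021, so the deposited log2 values had been quantile normalized, the array medians all lay at 6.91, and the dim probes gathered near 6.79, so the background had not been subtracted. Changes of dim genes are therefore understated. A second table with 73 signal columns and 73 detection p columns names its arrays by codes that match no sample label, so no column could be assigned to a group and it was not used here. The normalization planned before the data were examined, neqc with detection p values, needed that table, and so did the planned detection filter; the deposited log2 values took their place.

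A background limit of 7.05 was set at the mode of the probe means (6.79) plus 3 times their spread below the mode (0.086, as an SD). Probes above the limit on every array of at least 1 group of 2 or more arrays were kept (19626), which stands in for the detection filter and was chosen after seeing the data. Gene symbols came from the annotation of the array, brought to current names; 14980 of the kept probes named 1 gene, 4646 did not, and the brightest probe of each gene gave 11280 genes tested. A gene whose untreated arrays all lay below the limit has its rise given as a lower bound, the treated mean over the limit.

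Group means were fitted to all 73 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend; 37 residual and 10.4 prior degrees of freedom, median residual SD 0.092). All tests were two-sided. For each interferon against untreated, a moderated F test over the 7 times was adjusted by Benjamini-Hochberg over all genes, and a gene counted as changed at an adjusted p under 0.05 with a largest absolute log2 change of at least 1, its direction being that of the largest change. Counts per time point used the same limits on each time's own contrast. Between interferons, equal-weight means over 2, 4, 6, 12 and 24 h were compared at an adjusted p under 0.05 with no minimum change: IFN-β minus IFN-α, IFN-λ1 minus IFN-λ2, IFN-λ3 minus IFN-λ2, IFN-λ1 minus IFN-λ3 and type I minus type III. Persistence was the change from 6 to 24 h, type III minus type I; the same for IFN-β minus IFN-α was added after seeing the data. All comparisons with untreated cells share the same 4 arrays, so their errors are not independent. Correlations of the b minus a differences between interferons at the same time lay between 0.57 and 0.76 at 2 and 4 h and between -0.031 and 0.31 at the other times. At 2, 4 and 12 h every pair of interferons correlated above 0.1 (lowest 0.16 at 12 h), at 0.5, 6 and 24 h not every pair did (lowest 0.043, 0.047 and -0.031), and across all times 248 of 561 pairs did. The letters thus go together at some times only and were not treated as pairs; the fit with letter within time as a block stands beside the counts that it moved.

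An antiviral ISG score was the mean log2 value of the list on an array. Its differences over 2 to 24 h were tested by exact permutation of the interferon labels within each time (7776 or 3888 arrangements) or, for type I minus type III, with 1e+05 resamples, adjusted by Benjamini-Hochberg over the 5 contrasts. Before the data were examined, 24 gene lists were written with 407 genes, of which 316 were tested: antiviral ISGs, receptors and signal chain, negative regulators, viral RNA and DNA sensing, MHC class I, MHC class II, chemokines and cytokines, guanylate-binding proteins and related genes, immediate early genes, NF-kB targets, apoptosis (the cell death genes), cell cycle, hepatocyte function, acute phase, cholesterol, unfolded protein response, hypoxia and glycolysis, heat shock, hepatitis virus entry factors, interferon genes, markers of leukocytes, stellate cells and endothelium, and reference genes. The 21 lists with at least 5 tested genes were compared with all other genes by camera with a preset correlation of 0.01, adjusted over the lists within a contrast, and again with an estimated correlation. Certain genes are not reported here.

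The genes named were chosen by a rule fixed before the data were examined: for each interferon the 10 largest rises and 3 largest falls with every array on 1 side of all 4 untreated arrays, the 8 largest differences in each direction for type I minus type III and for persistence, the 5 largest in each direction for the other contrasts, up to 4 called members of each list, and a fixed set named whatever its result (receptors, IRF1, IRF9, IFIT1, MX1, ISG15, USP18, SOCS1, CXCL10, ACTB and GAPDH). Genes named outside this rule, such as HERC5, OAS2, RSAD2, OASL, HLA-B and CXCL11 for single interferons and the 19 genes raised by all 5 interferons, were chosen after their values were seen.

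Alternatives fixed before the data were examined were no dim filter, no intensity trend, the replicate letter as a block, letter within time as a block, the mean of a gene's probes, only the arrays of the groups compared, the 10 arrays of 0.5 h as the baseline, other thresholds (adjusted p alone, or a log2 difference of at least 0.5), other time windows, a score without 5 members, camera with an estimated correlation, and leaving out each array in turn. Removal of background by normexp with an offset of 16, and leaving out the b arrays of 2 and 4 h, were added after seeing the data. For each contrast with at least 3 arrays on a side, 100 regroupings of the arrays, the real one among them, were counted (18 for persistence of IFN-β minus IFN-α). The pipeline was tested on simulated data: with 50 genes moved by a log2 of 1 and 50 by 2, 96% and 100% were recovered for IFN-β against untreated with 0 false calls, and changes of 0.25 were recovered at 90% for IFN-β minus IFN-α with 8 false calls. The simulated noise was drawn independently for each gene and array with the gene's residual SD. It held no shift of the b arrays of 2 and 4 h and no outlying untreated array. False calls from such structure were therefore not measured. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.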

Results

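Gene expression was measured with Illumina bead arrays in Huh7 cells, a human hepatoma line used as a model of hepatocytes. The cells were left untreated (4 arrays) or treated with 1 of 5 interferons for 0.5, 1, 2, 4, 6, 12 or 24 h. IFN-α and IFN-β, the type I interferons, were given at 500 U/ml, and IFN-λ1, IFN-λ2 and IFN-λ3, the type III interferons, at 10 ng/ml. Each of the treated groups held 2 arrays, except IFN-λ3 at 4 h with 1, which made 73 arrays in 36 groups. Every array had a median log2 signal of 6.91, and 35.9% of its probes lay above the background limit. Arrays of a treated pair correlated at r = 0.99 to 0.998 across genes and the untreated arrays at 0.991 to 0.995; genes are not independent replicates. The number of arrays limits the precision. Each interferon was given at 1 dose and the doses of the types are in different units, so the part of dose in the difference between the types was not tested.

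The principal components of the 73 arrays, of which the largest held 42.2% of the variance, showed another feature: the second (12.8%) separated the 9 b arrays of 2 and 4 h from all the others. Those arrays had values of 12.8 to 17.6 on the second component, against -7.3 to 5.83 for the other arrays. Of 195 genes with a mean difference of at least 0.5 between the b and a arrays at 2 h, 0 were on the list of antiviral interferon-stimulated genes (ISGs; chance gives 0.743), and 6 were among the 269 genes that an interferon raised (chance gives 4.65). At 4 h there were 147 such genes, 0 of them antiviral ISGs (chance gives 0.56) and 7 raised by an interferon (chance gives 3.51). Without these arrays, 139 genes changed with IFN-α and 310 with IFN-β, as with them, and IFN-β differed from IFN-α in 1467 genes instead of 1646.

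**Figure D1:**
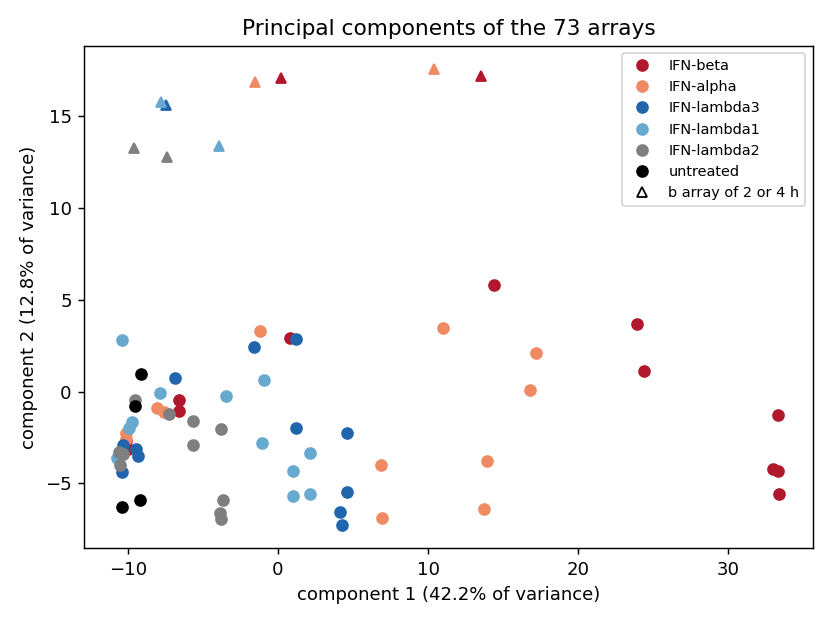
Each point is 1 of the 73 arrays, placed by its scores on the first 2 principal components of the log2 values (percent of variance on each axis), colored by interferon, with triangles for the b arrays of 2 and 4 h. Component 1 carries 42.2% of the variance, and the 9 triangles lie at 12.8 to 17.6 on component 2, above all other arrays (-7.3 to 5.83).

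Which genes each interferon changes, and when, was asked of the comparisons with untreated cells. IFN-α raised antiviral effectors most. MX1, a GTPase that traps incoming viral nucleocapsids, rose by a log2 of 6.23 ± 0.10 at 12 h (SE, 2 arrays against 4; adjusted p = 7.3e-48) from an untreated log2 level of 7.28 ± 0.11 (SD, n = 4). IFIT1, which binds viral RNA with a foreign cap, rose by 5.95 ± 0.093 at 6 h and its relatives IFIT2 and IFIT3 by 5.02 ± 0.082 at 4 h and 4.08 ± 0.085 at 6 h. IFI6 rose by 5.47 ± 0.096 at 24 h, and the ubiquitin-like modifier ISG15 by 4.27 ± 0.083 at 12 h. UBE2L6, the enzyme that conjugates ISG15, rose by 4.25 ± 0.11 at 12 h, and HELZ2, a helicase that acts as a nuclear receptor coactivator, by 4.44 ± 0.13 at 6 h. TAP1, a peptide pump of antigen presentation, rose by 4.90 ± 0.12 at 6 h. Where all 4 untreated arrays of a gene lay below the background limit, the fold is a lower bound, the treated mean over that limit. By this measure SLC15A3, a lysosomal peptide transporter, rose at least 18.8-fold at 12 h. HERC5, the ligase for ISG15, rose at least 11.2-fold at 6 h, and OAS2, which makes the activator of RNase L, at least 11.1-fold at 12 h. In all, 139 genes changed with IFN-α at 1 or more time points by at least a log2 of 1 (133 rose and 6 fell). Among the 133 that rose, the largest change came at 6 h in 57 and at 12 h in 38.

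The 3 largest falls with IFN-α were in TNFRSF10D, a decoy receptor for the death ligand TRAIL (-1.26 ± 0.11 at 12 h, adjusted p = 1.5e-14), AKR1C2 and H4C3. AKR1C2 encodes an enzyme of steroid metabolism (-1.14 ± 0.19 at 12 h, adjusted p = 4.6e-05) and H4C3 a histone (-1.09 ± 0.32 at 12 h, adjusted p = 0.0017). Each was fragile. TNFRSF10D fell short of a log2 of 1 with the arrays of 0.5 h as the baseline (-0.986), AKR1C2 without untreated array c (-0.768), and H4C3 without array a of IFN-α at 12 h (-0.684). Without the fold limit, TNFRSF10D and AKR1C2 were lower than untreated with all 5 interferons at 12 and at 24 h. All untreated arrays belong to time 0, so a change with time in culture is not separated from the treatment here.

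With IFN-β, the same effectors rose further, several of them until 24 h. MX1 rose by 6.83 ± 0.10 at 24 h (SE, 2 arrays against 4; adjusted p = 1.5e-49) and IFI6 by 6.37 ± 0.096 at 24 h. IFIT1 rose by 6.24 ± 0.093 at 12 h, IFIT2 by 6.11 ± 0.082 at 6 h and TAP1 by 5.98 ± 0.12 at 12 h. Genes dark in untreated cells included OAS2 (at least 68.9-fold at 24 h), SLC15A3 (at least 53.8-fold), IFI27 (at least 43.6-fold) and the membrane protein IFITM1, which blocks the entry of viruses (at least 36-fold). CXCL10, a chemokine that attracts T cells, rose by 5.66 ± 0.072 at 12 h, against 3.54 ± 0.072 at 6 h with IFN-α. IFN-β changed 310 genes, of which 267 rose and 43 fell. Among the 267 that rose, the largest change came at 12 h in 94 and at 24 h in 102. The falls were led by ACO1, the iron-dependent aconitase of the cytosol (-1.85 ± 0.082 at 24 h, adjusted p = 1.2e-25). AKR1C2 (-1.84 ± 0.19 at 24 h, adjusted p = 6.1e-11) and the long noncoding RNA DANCR (-1.56 ± 0.087 at 12 h, adjusted p = 1.1e-22) came next.

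The type III interferons raised a subset of these genes. With IFN-λ1, MX1 rose by 5.80 ± 0.10 at 24 h (SE, 2 arrays against 4; adjusted p = 2.2e-45) and IFI6 by 4.94 ± 0.096 at 24 h. IFIT1 rose by 4.86 ± 0.093 at 12 h and ISG15 by 3.78 ± 0.083 at 24 h. EPSTI1 (3.06 ± 0.071), HELZ2 (2.94 ± 0.13), PARP9 (2.67 ± 0.11) and IRF9, the DNA-binding part of the main interferon transcription factor (2.66 ± 0.10), peaked at 12 h. IFITM3 (2.85 ± 0.090) and IFITM2 (2.60 ± 0.074) peaked at 24 h. IFN-λ3 moved the same genes somewhat further: MX1 by 6.10 ± 0.10 at 24 h, IFI6 by 5.41 ± 0.096 at 24 h, IFIT1 by 5.06 ± 0.093 at 12 h, and ISG15 by 4.13 ± 0.083 at 24 h. IFITM3 rose by 3.40 ± 0.090 at 24 h, EPSTI1 by 3.33 ± 0.071 at 12 h and HELZ2 by 3.32 ± 0.13 at 6 h. The rises of IFITM2, UBE2L6 and TAP1 were 3.10 ± 0.074 at 24 h, 3.07 ± 0.11 at 24 h and 2.91 ± 0.12 at 12 h. IFN-λ2 was the weakest. It raised MX1 by 4.51 ± 0.10 at 24 h (adjusted p = 7.5e-40), IFI6 by 3.64 ± 0.096 at 24 h, IFIT1 by 3.51 ± 0.093 at 12 h and ISG15 by 2.88 ± 0.083 at 24 h. IRF9 rose by 2.36 ± 0.10 at 12 h, HELZ2 by 1.93 ± 0.13 at 12 h, and PARP9 by 1.81 ± 0.11 at 12 h. For EPSTI1 the rise was 1.73 ± 0.071 at 12 h, for IFITM3 1.73 ± 0.090 at 24 h and for IFITM2 1.57 ± 0.074 at 24 h.

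IFN-λ1 changed 47 genes (46 rose, 1 fell), IFN-λ2 changed 22 (21 rose, 1 fell) and IFN-λ3 changed 59 (58 rose, 1 fell). The single fall with IFN-λ1 was AKR1C2 (-1.03 ± 0.19 at 12 h, adjusted p = 0.0025). AKAP12, a scaffold of protein kinase A, was the single fall with IFN-λ2 (-1.16 ± 0.12 at 24 h, adjusted p = 6.8e-09) and IFN-λ3 (-1.05 ± 0.12 at 24 h, adjusted p = 7.5e-09). Removing 1 array ended each of these calls: AKR1C2 was at -0.663 without untreated array c and at -0.994 without array a of IFN-λ1 at 12 h, and AKAP12 was at -0.993 and -0.888 without untreated array b. The mean of its 4 probes gave -0.549 and -0.485, with the weakest probe at -0.04 and -0.0366, and the 0.5 h baseline gave -0.805 and -0.7. With the background subtracted, a setting chosen after seeing the data, the counts were 211 genes for IFN-α, 492 for IFN-β, 83 for IFN-λ1, 50 for IFN-λ2 and 95 for IFN-λ3.

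The number of raised genes per time point differed in shape between the interferons. With IFN-α it went from 42 genes at 2 h to 103 at 6 h and back to 55 at 24 h. With IFN-β it went from 52 at 2 h to 168 at 6 h, 210 at 12 h and 196 at 24 h. IFN-λ1 raised 10 genes at 2 h, 34 at 12 h and 31 at 24 h, and IFN-λ3 raised 13, 42 and 45. With IFN-λ2 the counts were 9 at 6 h, 14 at 12 h and 14 at 24 h; at 2 h the count was 5, and 9 without array a of that group or 3 without untreated array c. At 0.5 and 1 h the counts were at most 25 and moved with single arrays: IFN-α raised 10 genes at 1 h, and 16 without untreated array d.

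**Figure D2:**
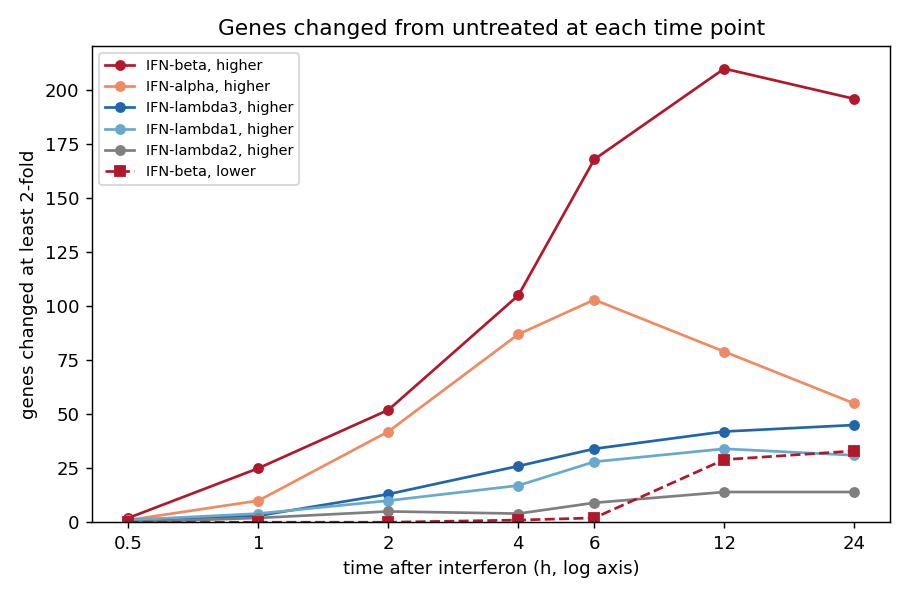
Lines join the number of genes (vertical axis) that were higher than in untreated cells by at least a log2 of 1 at an adjusted p under 0.05, by hours of treatment on a log axis, for each interferon. The dashed line gives the genes lower with IFN-β. The count for IFN-α peaks at 103 genes at 6 h, and that for IFN-β reaches 210 at 12 h.

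The antiviral ISG list, 43 genes written before the data were examined, rose almost whole with type I interferons: 37 members with IFN-α and 40 with IFN-β, against 22 with IFN-λ1, 10 with IFN-λ2 and 28 with IFN-λ3. Among its members, RSAD2, which makes a chain terminator of viral RNA synthesis, rose at least 3.39-fold with IFN-α and 15.6-fold with IFN-β, and OASL at least 9.58-fold and 20.5-fold; neither was called with a type III interferon. Other probes of some members moved far less, for IFIT1 by 1.69 with IFN-α and 0.26 with IFN-λ2, for OAS1 by 0.31 with IFN-α and 0.108 with IFN-λ1 and for OAS2 by 0.0754 with IFN-λ1; the cause was not tested. For this list, and for every other, the counts against untreated adjusted over the list alone were the same as those over all genes tested. As a set, the list lay above the other genes with each interferon (limma's camera test, two-sided, adjusted p from 4.9e-225 for IFN-λ3 to 3.8e-69 for IFN-λ2).

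Of the 10 receptor and signal chain genes tested, IRF9 passed a log2 of 1 with every interferon and IRF1 with all but IFN-λ2, where it reached 0.85 ± 0.11 (adjusted p = 6.4e-06). IRF1, a transcription factor that acts before the late ISGs, peaked at 2 h: by 2.95 ± 0.11 with IFN-α, 3.36 ± 0.11 with IFN-β, 1.10 ± 0.11 with IFN-λ1 and 1.28 ± 0.11 with IFN-λ3. The call with IFN-λ1 was lost without array a of that group (0.892), without untreated array c (0.998) and with the 0.5 h baseline (0.841). IRF9 peaked at 2.93 ± 0.10 with IFN-α and 3.10 ± 0.10 with IFN-β, and at 24 h it still stood at 2.60, 3.08, 2.37, 2.13 and 2.55 with IFN-α, IFN-β, IFN-λ1, IFN-λ2 and IFN-λ3. No receptor gene changed by a log2 of 1 as reported; with the background subtracted IFNLR1 did with IFN-β (1.23). IFNLR1, the specific chain of the type III receptor, moved most, by 0.85 ± 0.074 at 6 h with IFN-β (adjusted p = 3.1e-14) and 0.46 ± 0.074 at 2 h with IFN-α (adjusted p = 1.4e-05), from an untreated level of 7.54 ± 0.051. IFNAR1 changed by -0.56 ± 0.10 at 24 h with IFN-β (adjusted p = 0.00022), and IFNAR2 and IL10RB stayed within 0.33 of their untreated level with either type I interferon.

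The feedback inhibitor USP18, which detaches the kinase JAK1 from the type I receptor, was the only 1 of 10 negative regulators raised by all 5 interferons. USP18 rose by 3.37 ± 0.10 and 3.77 ± 0.10 with IFN-α and IFN-β and by 2.14 ± 0.10, 1.14 ± 0.10 and 2.44 ± 0.10 with IFN-λ1, IFN-λ2 and IFN-λ3. With IFN-β, SOCS1 rose at least 2.76-fold and SOCS3 by 1.19 ± 0.055 at 1 h (0.776 as the mean of its probes), while the phosphatase PTPN11 went the other way, by -1.09 ± 0.081 at 24 h. Among 11 sensors of viral nucleic acid, IFIH1 and RIGI passed a log2 of 1 with every interferon but IFN-λ2, where they reached 0.97 ± 0.073 and 0.51 ± 0.061 (adjusted p = 7.4e-18 and 1.9e-08). RIGI rose by 2.14 ± 0.061, 2.46 ± 0.061, 1.06 ± 0.061 and 1.23 ± 0.061 with IFN-α, IFN-β, IFN-λ1 and IFN-λ3, and IFIH1 at least 13.8-fold, 19.1-fold, 4.12-fold and 5.27-fold. The adaptor MYD88 passed a log2 of 1 with the type I interferons (1.73 ± 0.083 and 2.36 ± 0.083) and stayed below it with IFN-λ1 and IFN-λ3 (0.58 ± 0.083 and 0.80 ± 0.083, adjusted p = 2e-08 and 3.5e-12). DHX58, TLR3 and TICAM1 (its other probe at 0.307) passed with IFN-β; IFN-λ2 raised 0 sensors (limma; 3 at an unadjusted p under 0.05 without a fold limit).

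Antigen presentation by MHC class I separated the types by the number of members past a log2 of 1. At an unadjusted p under 0.05 without a fold limit (limma F test), 17 of 17 members changed with IFN-α and 16 with IFN-β. By that measure 8, 2 and 10 changed with IFN-λ1, IFN-λ2 and IFN-λ3. IFN-β raised 14 of 17 members and IFN-α raised 9, whereas with IFN-λ1 and IFN-λ3 only TAP1 passed (2.41 ± 0.12 and 2.91 ± 0.12) and with IFN-λ2 0 did (limma; 2 at an unadjusted p under 0.05 without a fold limit; TAP1 0.86 ± 0.12, adjusted p = 1.3e-06). The immunoproteasome subunits PSMB8 and PSMB9 rose at least 5.3-fold and 3.36-fold with IFN-α and 12.8-fold and 9.28-fold with IFN-β. Their weakest probes gave a log2 of 0.0199 and 0.165 with IFN-α and 0.229 and 0.598 with IFN-β; all 4 calls held as the mean of their probes. HLA-E rose by 2.32 ± 0.077 and 3.88 ± 0.077, and HLA-B rose at least 7.36-fold with IFN-β. The list of guanylate-binding proteins and related genes followed the same order, with 6 of 17 raised by IFN-α, 13 by IFN-β, 3 by IFN-λ1 and 4 by IFN-λ3. IFN-λ2 raised 0 of the 17 (limma; 5 at an unadjusted p under 0.05 without a fold limit). GBP1, a GTPase that coats intracellular pathogens, rose by 3.37 ± 0.14, 3.98 ± 0.14, 1.45 ± 0.14 and 1.60 ± 0.14 with IFN-α, IFN-β, IFN-λ1 and IFN-λ3. LAP3 passed with IFN-λ3 (1.03 ± 0.095 at 24 h), but at 0.996 without untreated array b or d and 0.979 without array a of IFN-λ3 at 24 h. Of 3 MHC class II genes, 0 changed (limma; 1 with IFN-α and 2 with IFN-β at an unadjusted p under 0.05 without a fold limit).

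Some chemokines and cytokines passed a log2 change of 1 with type I interferons. IFN-α raised 3 of 14 and IFN-β 8, among them CXCL10, the death ligand TNFSF10 (at least 6.92-fold and 19.5-fold) and IL15 (1.56 ± 0.092 and 1.84 ± 0.092). IFN-β also raised CXCL11 (at least 2.36-fold) and CXCL2 (1.63 ± 0.092 at 1 h). IL18BP, a scavenger of IL18, rose by 2.32 ± 0.060 at 24 h with IFN-β on its brighter probe, while its other probe gave -0.111. CCL20 rose by 1.07 ± 0.12 at 12 h, and by 0.986 without untreated array c. The type III interferons raised 0 of the 14 (limma; 7, 5 and 6 at an unadjusted p under 0.05 without a fold limit with IFN-λ1, IFN-λ2 and IFN-λ3). With these CXCL10 moved by 0.31 ± 0.072, 0.14 ± 0.072 and 0.48 ± 0.072 at most. As a set over 2 to 24 h the list was called with IFN-λ3 (camera adjusted p = 0.0114), but not without untreated array b (0.0966) or c (0.0729). Among 15 NF-kB targets, IFN-α raised NFKBIZ (1.25 ± 0.094 at 2 h) and BCL3 (1.27 ± 0.20 at 2 h, and 0.869 without array b of that group). IFN-β raised these (2.16 ± 0.094 and 1.64 ± 0.20) with CXCL2 and CCL20. The type III interferons raised 0 of the 15 (limma; 9, 12 and 10 at an unadjusted p under 0.05 without a fold limit). NFKBIZ with IFN-α was at 0.692 with the 0.5 h baseline.

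A few cell death genes rose with type I interferons. Of 17 tested, IFN-α raised TNFSF10 and MLKL, the executor of necroptosis (at least 3.22-fold). IFN-β raised these (MLKL at least 9.22-fold) with CASP1 (at least 4.53-fold) and CASP4 (1.62 ± 0.078 at 12 h; 0.838 as the mean of its 3 probes, the lowest at -0.124). The type III interferons raised 0 (limma; 2, 2 and 4 at an unadjusted p under 0.05 without a fold limit). CFB, a complement protease made by the liver, was raised by 1.14 ± 0.092 at 6 h with IFN-α (0.86 with the 0.5 h baseline) and 3.07 ± 0.092 at 24 h with IFN-β. HAMP, the iron hormone hepcidin, rose by 1.22 ± 0.074 at 2 h with IFN-β. Of the 12 acute phase genes, the type III interferons raised 0 (limma; 4, 6 and 6 unadjusted, without a fold limit). At 24 h HAMP and the cholesterol gene HMGCS1 were higher than untreated with all 5 interferons without the fold limit. Single members of other lists passed a log2 of 1 only with IFN-β. They were HMGCS1 of 14 cholesterol genes (1.20 ± 0.099 at 24 h; 0.995 with the 0.5 h baseline) and, of 16 hypoxia and glycolysis genes, PFKFB4 (1.05 ± 0.066 at 12 h) and ADM (1.03 ± 0.10 at 1 h; 0.908 without array b of IFN-β at 1 h and 0.916 without untreated array c). Of 5 leukocyte markers, IFN-β raised CD68 (2.45 ± 0.072 at 24 h) and CD14 (1.03 ± 0.098 at 24 h; 0.979 without untreated array d).

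A minority of the immediate early genes, which answer many stimuli within an hour, rose with each interferon. EGR1 peaked at 1 h with 1.85 ± 0.29, 2.66 ± 0.29, 1.73 ± 0.29, 1.63 ± 0.29 and 1.70 ± 0.29 for IFN-α, IFN-β, IFN-λ1, IFN-λ2 and IFN-λ3. Its untreated level of 8.07 ± 1.30 (SD, n = 4) varied widely between arrays. FOS rose by 1.79 ± 0.20, 2.91 ± 0.20 and 1.14 ± 0.20 with IFN-α, IFN-β and IFN-λ1, the last at 0.986 without untreated array c. FOSB rose by 1.17 ± 0.14, 1.27 ± 0.14, 1.20 ± 0.14, 1.22 ± 0.14 and 1.19 ± 0.14. ATF3 rose by 1.36 ± 0.12 and 1.69 ± 0.12 with the type I interferons and by 1.11 ± 0.12 and 1.02 ± 0.12 with IFN-λ2 and IFN-λ3. The latter 2 calls were lost without untreated array c (0.949 and 0.854) and, for IFN-λ3, without untreated array a (0.947). In total 5, 8, 3, 3 and 3 of the 20 members passed; without untreated array d the last 3 counts were 6, 5 and 5. No untreated array was taken after time 0, so a change with time in culture that all interferons share is not separated from a treatment effect in a comparison with untreated cells. Interferons compared at the same time share that age.

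Several lists stayed below a log2 change of 1 with every interferon. Of 25 cell cycle genes, 18 hepatocyte genes, 15 genes of the unfolded protein response and 11 heat shock genes, 0 were called (limma). So it was for 7 hepatitis virus entry factors, 5 stellate cell markers, 1 endothelial marker and 10 reference genes (0 called, limma). At an unadjusted p under 0.05 and without a fold limit, IFN-β changed 21, 15, 12, 8, 5, 3, 0 and 5 of them. ACTB and GAPDH moved by at most 0.068 ± 0.046 and -0.19 ± 0.083 with IFN-α (adjusted p = 0.56 and 0.28) and by 0.11 ± 0.046 and -0.17 ± 0.083 with IFN-β (adjusted p = 0.15 and 0.39). None of the 8 interferon genes had a probe above background. As a set over 2 to 24 h, heat shock genes lay below the other genes with IFN-λ1, IFN-λ2 and IFN-λ3 (camera adjusted p = 0.0039, 1e-05 and 0.0032; with IFN-λ1 0.067 without untreated array a), and cell cycle genes did with IFN-β (adjusted p = 0.00018). Of the 252 list results against untreated and between interferons, 234 kept their side of the threshold with an estimated correlation, among them every call for the antiviral ISGs. Lost against untreated were the immediate early genes with IFN-β (adjusted p = 0.2 with an estimated correlation). So were the NF-kB targets with IFN-λ1, IFN-λ2 and IFN-λ3 (0.08, 0.17 and 0.076), the acute phase genes with IFN-λ1 (0.3) and the hepatocyte genes with IFN-λ2 and IFN-λ3 (0.11 and 0.075). The negative regulators with IFN-λ1 had a median of -0.0035 below a mean of 0.172 and an upward test, the only list called against untreated in which these differed in sign.

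Whether the interferons differ in their targets or only in the size of the response was asked of the genes raised by 1 or more of them. All 60 genes raised by a type III interferon were also raised by a type I interferon, where independent calls would share 1.43. Because both types were compared with the same untreated arrays, the overlap was repeated with untreated arrays a and b for type I and c and d for type III. This gave 59 of 61, and the pairs exchanged gave 57 of 62. All untreated arrays belong to time 0, so a change with time in culture that all interferons share can still add to the overlap. The genes raised by all 5 interferons were 19: RND1, MX1, IFITM2, PARP14, EIF2AK2, IFIT1, PARP9, SP110, IRF9, FOSB, EGR1, TIPARP, BHLHE40, HELZ2, IFITM3, ISG15, IFI6, EPSTI1 and USP18. Raised here refers to the time of the largest change. EGR1 peaked at 1 h, and its mean log2 change over 2 to 24 h across the interferons was -0.482. A log2 of 1 was passed with IFN-β only in 136 genes, with IFN-α only in 1 and with a single type III interferon in 0 (limma). Few of the 136 answered IFN-β only: without the fold limit, 130 of them were also called higher than untreated with IFN-α, 32 with IFN-λ1, 25 with IFN-λ2 and 50 with IFN-λ3, and 6 with none of these. In the test of IFN-β minus IFN-α over 2 to 24 h, 124 of the 136 were higher with IFN-β. By mean change over 2 to 24 h, 165 of the 269 raised genes (61.3%) stood in the order IFN-β, IFN-α, IFN-λ3, IFN-λ1, IFN-λ2, and both type I interferons exceeded all type III interferons in 257. IFN-β raised 267 of the 269, so its place follows largely from their choice, and the order was not tested on them.

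An antiviral ISG score, the mean log2 signal of the 43 list members on an array, gave each interferon a time course. Over untreated arrays, whose SD was 0.032, the score was higher by 0.285 with IFN-α and 0.368 with IFN-β at 1 h. IFN-α reached 2.35 at 6 h and went down to 1.75 at 24 h, while IFN-β went on from 2.66 at 6 h to 3.47 at 24 h. IFN-λ1 reached 1.33 at 12 h, IFN-λ2 0.735 at 24 h and IFN-λ3 1.59 at 24 h.

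**Figure D3:**
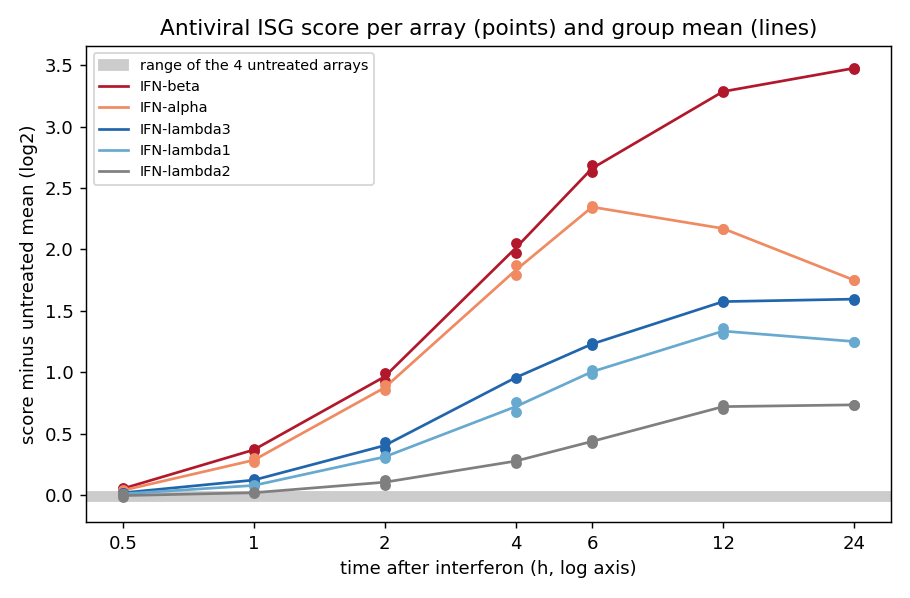
Points are the arrays' antiviral ISG scores (mean log2 signal of 43 genes) minus the untreated mean, against hours of treatment on a log axis. Lines join the means of each interferon, and the gray band is the range of the 4 untreated arrays. IFN-β climbs to 3.47 at 24 h, while IFN-α falls back from 2.35 at 6 h to 1.75.

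The type I interferons were compared at the same units per ml over 2 to 24 h. IFN-β induced more of the chemokine CXCL10 than IFN-α (log2 difference 2.33 ± 0.037, 10 arrays each, adjusted p = 2.8e-43), and of IFIT2 (2.20 ± 0.043, adjusted p = 1.1e-39). TNFSF10 (1.75 ± 0.040), OASL (1.68 ± 0.035) and RSAD2 (1.51 ± 0.038) were higher as well. IFIT3 (1.42 ± 0.044), MLKL (1.50 ± 0.031), TAP1 (1.28 ± 0.059), HLA-E (1.16 ± 0.040), IRF1 (1.11 ± 0.058), PSMB8 (1.07 ± 0.033) and CFB (1.03 ± 0.047) followed. The differences of genes near background are understated because the signal there is mostly background. Smaller gaps lay in IFIH1 (0.80 ± 0.038), ATF3 (0.67 ± 0.064), SOCS1 (0.63 ± 0.041), CD68 (0.64 ± 0.037), USP18 (0.59 ± 0.053), HAMP (0.58 ± 0.038) and IFNLR1 (0.32 ± 0.038). IRF9 differed by only 0.20 ± 0.054 (adjusted p = 0.0076), a call lost over 4 to 12 h (0.178). Of the antiviral ISGs, 40 of 43 were higher with IFN-β (42 adjusted over the list alone), as were 16 of 17 MHC class I genes (16 alone), and 17 of 17 guanylate-binding proteins and related genes (17). The counts were 8 of 14 for chemokines and cytokines (9), 8 of 11 for sensors (9), 10 of 17 for cell death genes (10), 7 of 12 for acute phase genes (8) and 6 of 15 for NF-kB targets (7). Camera called each of these sets, with the immediate early genes, whose call did not hold (adjusted p = 0.18 with an estimated correlation).

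Lower with IFN-β than with IFN-α were FIGNL2 (-0.53 ± 0.057, adjusted p = 1.9e-10), RASL12 (-0.41 ± 0.064), the sialidase NEU4 (-0.40 ± 0.069), ACO1 (-0.39 ± 0.042) and the mitochondrial carrier SLC25A42 (-0.38 ± 0.053). The second probe of FIGNL2 changed by -0.105 with IFN-β at 12 h, against -1.34 for the first. Cell cycle genes followed: 0 of 25 were higher and 13 lower (15 adjusted over the list alone; 0 higher and 16 lower at an unadjusted p under 0.05, limma; camera adjusted p = 4.6e-07). TOP2A was at -0.31 ± 0.065, RRM2 at -0.29 ± 0.047, BIRC5 at -0.24 ± 0.051 and AURKA at -0.23 ± 0.048. Over 4 to 12 h these 4 lost their call, at -0.212, -0.177, -0.163 and -0.182. The total was 1646 genes (832 higher, 814 lower), of which 118 were higher and 1 lower by at least 0.5; the count was 819 over 4 to 12 h and 2758 with the replicate letter within each time as a block. The ISG score differed by 0.684 (exact permutation p = 0.000257, two-sided, adjusted 0.000257, the smallest the arrangement allows), with IFN-β higher at 5 of 5 times.

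Whether the type III interferons differ at the same mass was asked within that family. IFN-λ1 exceeded IFN-λ2 in IFIT1 (1.71 ± 0.048, 10 arrays each, adjusted p = 7e-32), MX1 (1.29 ± 0.054), IFI6 (1.17 ± 0.050), ISG15 (1.11 ± 0.043) and HELZ2 (1.05 ± 0.066). The same held for TAP1 (0.98 ± 0.059), IFIH1 (0.91 ± 0.038), USP18 (0.78 ± 0.053), GBP1 (0.52 ± 0.073) and IRF9 (0.37 ± 0.054). The protein disulfide isomerase relative TXNDC12 was lower (-0.21 ± 0.035, adjusted p = 9.8e-05). The other 3 lower genes, NT5DC2 (-0.17), HSD17B2 (-0.15) and SLC45A4 (-0.12), each lost their call without any of several arrays. Examples are -0.143 for NT5DC2 without array a of IFN-λ1 at 4 h, -0.13 for HSD17B2 without array a of IFN-λ2 at 2 h and -0.105 for SLC45A4 without array a of IFN-λ2 at 4 h. In total 75 genes differed (71 higher, 4 lower; 123 with letter within time as a block). They held 34 of 43 antiviral ISGs (35 adjusted over the list alone), 3 of 11 sensors (4) and 2 of 17 MHC class I genes (6). They also held 2 of 14 chemokines and cytokines (3) and 4 of 17 guanylate-binding proteins and related genes (5). The 2 members of the chemokine and cytokine list were TNFSF10 and IL15, neither of them a chemokine. TNFSF10 lost its call without any of 3 arrays (limma adjusted p = 0.0556, 0.056 and 0.064). Without the b arrays of 2 and 4 h, TNFSF10 and IL15 both lost it (0.15 and 0.236). Camera calls for the signal chain, hepatocyte and acute phase genes were lost (adjusted p = 0.051, 0.18 and 0.19 with an estimated correlation). The score differed by 0.469 (exact permutation p = 0.000257, two-sided, adjusted 0.000257, the smallest possible), at 5 of 5 times.

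IFN-λ3 exceeded IFN-λ2 by more, in IFIT1 (2.10 ± 0.050, 9 arrays against 10, adjusted p = 4.6e-35), IFI6 (1.60 ± 0.052), UBE2L6 (1.54 ± 0.061), MX1 (1.53 ± 0.057) and TAP1 (1.49 ± 0.062). The second probe of IFI6 gave another order at 24 h, with 2.24, 2.76 and 1.81 over untreated for IFN-λ1, IFN-λ2 and IFN-λ3 and 1.83 and 0.631 for IFN-α and IFN-β. ISG15 (1.48 ± 0.045), IFIH1 (1.24 ± 0.040), USP18 (1.13 ± 0.055), GBP1 (0.64 ± 0.077), IRF9 (0.51 ± 0.057) and CXCL10 (0.24 ± 0.039, adjusted p = 1.8e-05) were higher too. TXNDC12 (-0.24 ± 0.037, adjusted p = 4.7e-06) and the DNA repair regulator CYREN (-0.23 ± 0.042, adjusted p = 0.00025) were lower. So was TRAK2 (-0.17), whose call was lost without any of 11 arrays (-0.157 without array a of IFN-λ3 at 2 h). The 100 genes that differed (97 higher, 3 lower; 176 with letter within time as a block) held 36 of 43 antiviral ISGs (38 adjusted over the list alone) and 8 of 17 MHC class I genes (9). They also held 7 of 17 guanylate-binding proteins and related genes (7) and 3 of 14 chemokines and cytokines (3). The score differed by 0.697 (exact permutation p = 0.000257, two-sided, adjusted 0.000257, the smallest possible), at 5 of 5 times.

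Between IFN-λ1 and IFN-λ3 the gap was small and in favor of IFN-λ3. IFIT3 (-0.57 ± 0.046, adjusted p = 2.4e-12), IFIT2 (-0.52 ± 0.045), UBE2L6 (-0.51 ± 0.061) and TAP1 (-0.51 ± 0.062) were lower with IFN-λ1 (10 arrays against 9). So were SLC15A3 (-0.47 ± 0.043), OAS1 (-0.45 ± 0.046), OAS2 (-0.45 ± 0.039), USP18 (-0.35 ± 0.055) and IFIH1 (-0.32 ± 0.040). SSPN, a membrane protein of the dystrophin complex, was the 1 gene higher with IFN-λ1 (0.20 ± 0.042, adjusted p = 0.0047), and its call rested on the lone IFN-λ3 array at 4 h (0.15 without it, adjusted p = 0.314). Of the 51 genes, 50 were lower with IFN-λ1 (130 genes with letter within time as a block), 27 of them among the 43 antiviral ISGs (36 adjusted over the list alone). They included 4 of 17 MHC class I genes (6 lower and 1 higher), 3 of 11 sensors (3) and 2 of 17 guanylate-binding proteins and related genes (3). These 3 counts rest on single arrays: MHC class I had 2 without any of 5 arrays (PSMB8 and PSMB9 went to adjusted p = 0.129 and 0.104 without array b of IFN-λ3 at 24 h). The sensors had 1 without the lone IFN-λ3 array at 4 h (MYD88 0.566, RIGI 0.136), and the guanylate-binding list 1 without any of 7 arrays. The acute phase genes had 0 called and 5 lower adjusted over the list alone and at an unadjusted p under 0.05 (limma; camera adjusted p = 1.4e-05). The hepatocyte list lost its call (adjusted p = 0.18 with an estimated correlation). The score differed by -0.228 (exact permutation p = 0.000257, two-sided, adjusted 0.000257, the smallest possible), at 5 of 5 times.

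What sets type I apart from type III interferons was asked of the mean of IFN-α and IFN-β minus the mean of the type III interferons, over 2 to 24 h (20 arrays against 29). Type I interferons induced far more IFIT2 (3.47 ± 0.028, adjusted p = 1.3e-57), CXCL10 (3.10 ± 0.024, adjusted p = 7.9e-58), TAP1 (3.00 ± 0.039) and SLC15A3 (2.78 ± 0.027). HERC5 (2.57 ± 0.024), OASL (2.48 ± 0.023), IFIT3 (2.46 ± 0.029) and OAS2 (2.42 ± 0.024) followed. HLA-E (2.31 ± 0.026), TNFSF10 (2.21 ± 0.026), IFIT1 (2.00 ± 0.031), PSMB8 (1.96 ± 0.022), GBP1 (1.93 ± 0.048), IFIH1 (1.90 ± 0.025) and MLKL (1.64 ± 0.021) came next. Of the genes that every interferon raised, MX1 differed by 1.34 ± 0.035, ISG15 by 1.29 ± 0.028, USP18 by 1.57 ± 0.035 and IRF9 by 0.53 ± 0.036. IRF1 (1.49 ± 0.038), CFB (1.27 ± 0.031), RIGI (1.07 ± 0.021), CD68 (0.95 ± 0.024), IL15 (0.86 ± 0.031), ATF3 (0.75 ± 0.042), SOCS1 (0.70 ± 0.027), NFKBIZ (0.51 ± 0.032) and IFNLR1 (0.33 ± 0.025) were higher too. IFNAR1 was lower by a little (-0.12 ± 0.034, adjusted p = 0.0031). IFNAR2, IL10RB, ACTB and GAPDH were not called (adjusted p = 0.48, 0.42, 0.45 and 0.35), but as the mean of their probes IL10RB (0.0552, adjusted p = 0.0287) and GAPDH (-0.0704, adjusted p = 0.00779) were. Of all 10 reference genes, 4 were lower with type I interferons (4 adjusted over the list alone) and 0 higher (limma; 0 at an unadjusted p under 0.05; camera adjusted p = 0.203).

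Lower with type I interferons were the ceramide kinase CERK (-0.55 ± 0.026, adjusted p = 1e-23), FIGNL2 (-0.54 ± 0.037), RASL12 (-0.53 ± 0.042) and NEU4 (-0.51 ± 0.045). Further lower genes were DANCR (-0.48 ± 0.029), CYREN (-0.47 ± 0.026), NT5DC2 (-0.47 ± 0.028) and CEBPA, a transcription factor of mature hepatocytes (-0.47 ± 0.040). Of 25 cell cycle genes, 17 were lower (20 adjusted over the list alone) and 0 higher (limma; 0 at an unadjusted p under 0.05; camera adjusted p = 2.5e-05). BIRC5 was at -0.30 ± 0.033, AURKA at -0.27 ± 0.032, TOP2A at -0.25 ± 0.042 and CCND1 at -0.22 ± 0.031. All 43 antiviral ISGs were higher (43 adjusted over the list alone), as were 16 of 17 MHC class I genes (16). The same held for 17 of 17 guanylate-binding proteins and related genes (17) and 10 of 14 chemokines and cytokines (11). Also higher were 12 of 17 cell death genes (12), 9 of 15 NF-kB targets (10), 7 of 11 sensors (9) and 8 of 12 acute phase genes (9). So were 11 of 20 immediate early genes (11), without a camera call once the correlation was estimated (adjusted p = 0.075 with an estimated correlation). In all 3752 genes differed (1410 higher, 2342 lower), 171 of them higher and 4 lower by at least 0.5. The number grew with time from 5 genes at 0.5 h and 57 at 1 h to 932 at 4 h and 2224 at 24 h. The ISG score differed by 1.29 (permutation p = 1e-05, two-sided, adjusted 5e-05, the smallest that 1e+05 resamples can give), at 5 of 5 times.

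**Figure D4:**
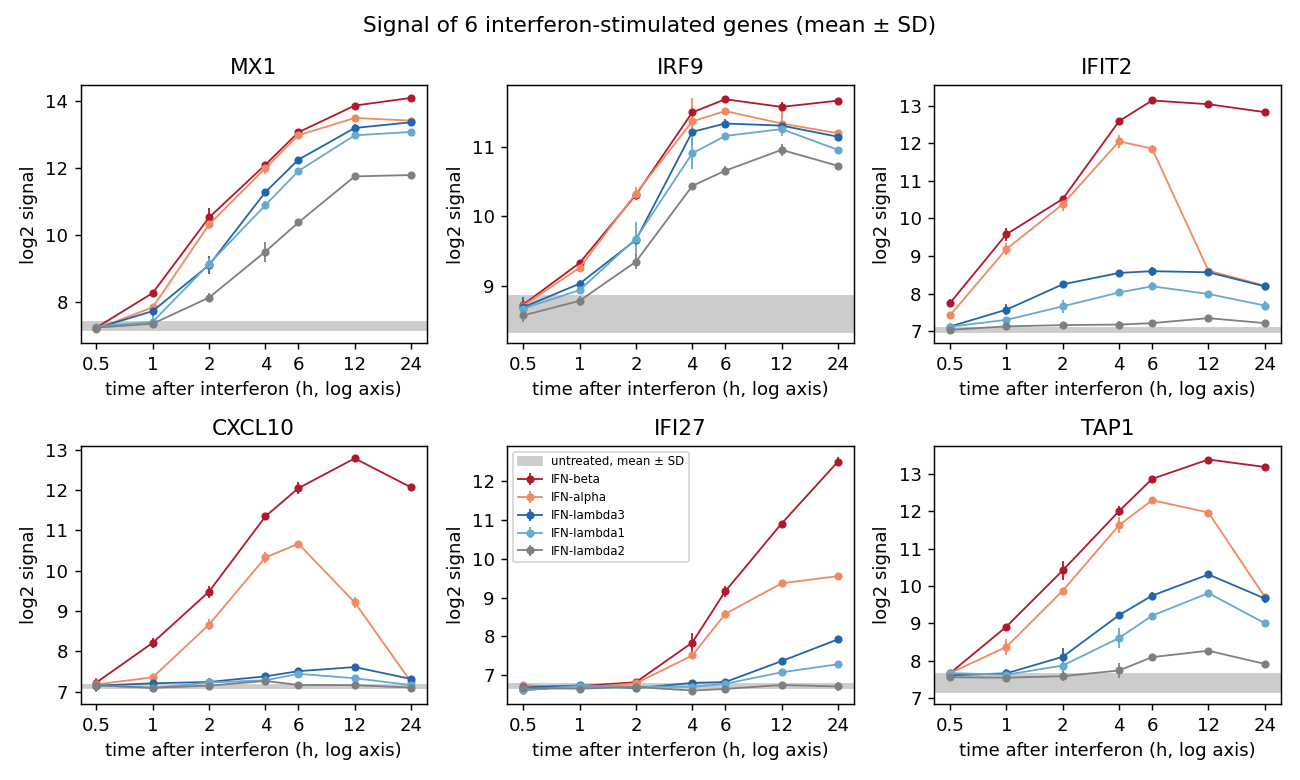
Each of the 6 panels shows the log2 signal of 1 gene by hours of treatment on a log axis, as the mean and SD of the arrays of each interferon, with the untreated mean and SD as a gray band. From 6 to 24 h, IFIT2 goes from 4.82 to 1.18 over untreated with IFN-α and from 6.11 to 5.79 with IFN-β, and CXCL10 from 3.54 to 0.11 and from 4.92 to 4.94. The type III interferons leave CXCL10 near its untreated level of 7.13.

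Whether the response to type III interferons lasts longer was asked of the change from 6 to 24 h, type III minus type I (12 arrays against 8 over the 2 times), which needs no untreated array. Of the genes that a type III interferon raised, IFIT2 was higher by this measure (1.68 ± 0.087, adjusted p = 1.2e-20), as were HERC5 (1.09 ± 0.075), PARP14 (1.05 ± 0.090), TAP1 (0.98 ± 0.12), IFIT3 (0.98 ± 0.089), GBP1 (0.91 ± 0.15) and USP18 (0.81 ± 0.11). CXCL10 (1.52 ± 0.075), TNFSF10 (1.37 ± 0.082), OASL (1.22 ± 0.072), APOL6 (0.92 ± 0.053), MLKL (0.71 ± 0.064) and IL15 (0.71 ± 0.097) were higher too, but were not called raised by a type III interferon. For them the value reads mainly the course with type I interferons. In the other direction, IFI27 rose more from 6 to 24 h with type I interferons (-1.60 ± 0.069, adjusted p = 2e-23), with the vitamin B12 carrier TCN1 (-1.40 ± 0.062), IFI44 (-1.08 ± 0.058) and IFITM1 (-1.02 ± 0.062). Others higher with type I interferons by this measure were HLA-B (-0.95 ± 0.066), HLA-H (-0.86 ± 0.080), TXNIP (-0.85 ± 0.078), HLA-F (-0.78 ± 0.071), CFB (-0.57 ± 0.097) and CD68 (-0.56 ± 0.076). Measured from 4 h instead of 6 h, HERC5 lost its call (0.0696) and MLKL changed sign (-0.191).

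Of the antiviral ISGs, 19 were higher by this measure with type III interferons, 17 of them raised by a type III interferon, and 8 with type I (22 and 8 adjusted over the list alone). The list's median was 0.238 (camera adjusted p = 9.5e-08), but from 4 h it turned to -0.0519 (adjusted p = 0.0294), so the direction depends on the early time point. Of the guanylate-binding proteins and related genes 7 were higher, 3 of them raised by a type III interferon, and 1 lower (8 and 1), and from 4 h the camera call was lost (0.0667, adjusted p = 0.0911). MHC class I went the other way with 3 and 6 of 17 (4 and 7), a camera call that was lost (adjusted p = 0.072 with an estimated correlation). Lost too were those of the sensors, the signal chain, the hepatocyte genes and the stellate cell markers (0.077, 0.1, 0.11 and 0.051). In total 696 genes differed (341 higher, of which a type III interferon raised 31, and 355 lower; 1822 with letter within time as a block), 73 of them higher and 30 lower by at least 0.5.

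This contrast averages over type I courses that differed, so the change from 6 to 24 h was also compared between IFN-β and IFN-α, a comparison added after the time courses were seen. IFN-β held CXCL10 by a log2 of 3.46 ± 0.12 more than IFN-α (4 arrays each, adjusted p = 2.2e-28), IFIT2 by 3.33 ± 0.13, OASL by 3.29 ± 0.11, HERC5 by 3.21 ± 0.12 and OAS2 by 3.18 ± 0.12. RSAD2 (3.10 ± 0.12), TAP1 (2.91 ± 0.19), SLC15A3 (2.90 ± 0.13), TNFSF10 (2.38 ± 0.13) and GBP1 (2.25 ± 0.23) showed the same. So did PSMB8 (2.17 ± 0.10), MLKL (2.08 ± 0.099), HLA-B (2.01 ± 0.10), IFIH1 (1.89 ± 0.12) and USP18 (1.15 ± 0.17). With IFN-α, IFIT2 stood at 4.82 over untreated at 6 h and 1.18 at 24 h, CXCL10 at 3.54 and 0.11, and TAP1 at 4.90 and 2.31; with IFN-β, IFIT2 stood at 6.11 and 5.79 and CXCL10 at 4.92 and 4.94. ACO1 (-1.30 ± 0.13, adjusted p = 1.4e-10), DANCR (-0.91 ± 0.14), NEU4 (-0.93 ± 0.22) and the nucleotide reductase subunit RRM2 (-0.69 ± 0.15) were lower with IFN-β by this measure.

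The antiviral ISGs that IFN-β held better were 36 of 43, with 0 the other way (38 and 0 adjusted over the list alone; limma, 38 and 0 at an unadjusted p under 0.05; camera adjusted p = 3.4e-124). The counts were 15 of 17 for MHC class I (16), 6 of 14 for the chemokines and cytokines (8), 5 of 17 for cell death genes (6) and 5 of 11 for the sensors (5). Of 25 cell cycle genes, 7 were lower with IFN-β (14 adjusted over the list alone; camera adjusted p = 1.4e-11). With each array left out in turn the 7 became 1 to 5, lowest without array b of IFN-β at 24 h; MCM6 went to an adjusted p of 0.213 without array a of IFN-α at 24 h. The total was 450 genes (296 higher, 154 lower; 1107 with letter within time as a block and 716 from 4 h instead of 6 h), of which 215 were higher and 87 lower by at least 0.5. From 6 to 24 h, 25 antiviral ISGs fell and 9 rose with IFN-α, against 2 and 27 with IFN-β, 6 and 15 with IFN-λ1, 1 and 16 with IFN-λ2 and 6 and 18 with IFN-λ3.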

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

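The tests of a shared batch, of a change of the cultures, of a uniformly weaker IFN-α response, both tests of the immediate early genes, the comparison of ISG scores between b and a arrays and the overlap of their differences with raised genes were chosen only after the result was seen; so was the comparison of IFN-β with IFN-α from 6 to 24 h.

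From 6 to 24 h, type III and type I interferons differed in 696 genes, by a test of the difference itself. Regrouping does not exclude chance as the source of a count this large: 4 of 100 regroupings reached it, the real one included. This share was not adjusted over the comparisons. The highest of the other regroupings called 1863 genes. That regrouping exchanged 4 of 4 type I arrays at 6 h and 1 at 24 h, and the others as large (1111 and 945 genes) 1 and 4, and 4 and 2. Exchanging 1 time more than the other brings the level difference between the types into the count, a structure of the arrays that comes from the interferons and not from a change with time. With letter within time as a block the real count was 1822.

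IFN-β and IFN-α differed in 450 genes from 6 to 24 h, again by a test of the difference. The design gives 18 regroupings, too few for a share under 0.05; 6 reached the real count, and the highest of the others called 1263, in a regrouping that exchanged both arrays at 6 h and 0 at 24 h; the other 4 (761 to 832) exchanged 1 at 6 h and 2 or 0 at 24 h. The pattern is that the IFN-α response fell after 6 h, with a score change of -0.595, while the score rose by 0.814 with IFN-β, 0.245 with IFN-λ1, 0.298 with IFN-λ2 and 0.361 with IFN-λ3. A wrong label on the IFN-α arrays of 24 h is argued against by the 12 h arrays, which already differed: 199 genes changed unlike from 6 to 12 h, 187 of them higher and 12 lower with IFN-β, 26 were antiviral ISGs, and 149 were also called from 6 to 24 h with the same sign. A change of all cultures after 6 h is argued against because the score fell with 1 interferon of the 5, and the same weaker response at every time because the ratio of the IFN-α to the IFN-β score was 0.882 at 6 h and 0.504 at 24 h. The arguments against a change of all cultures and a uniformly weaker response reuse the scores that showed the pattern, so they do not test the pattern independently. A fault shared by the IFN-α arrays of 12 and 24 h was not tested, since the replicates may be repeated arrays of 1 preparation. Causes in biology or dosing stay open too. IFN-α may have been used up, or may signal for a shorter time through the shared receptor. No later dose or receptor measurement was made to tell these apart.

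The b arrays of 2 and 4 h stood apart from all others. A swap of the 2 h and 4 h labels among them is argued against, since the ISG score was higher at 2 h than at 4 h in 0 interferons, and a different interferon response in those cultures as the source of the whole separation is too, since 0% of the 195 genes with a mean difference of at least 0.5 at 2 h were antiviral ISGs (chance gives 0.743 genes), and 6 were among the 269 genes that an interferon raised (chance gives 4.65). At 4 h, 0 of 147 were antiviral ISGs (chance gives 0.56), and 7 were raised by an interferon (chance gives 3.51), too few to make up the separation. The ISG score was still lower in the b array in 9 of 9 pairs at 2 and 4 h, by differences of -0.0875 to -0.0197, against 19 of 25 pairs at other times (-0.0634 to 0.0228), so a slightly weaker response in those arrays stays open. The differences between b and a arrays were alike across interferons, with a lowest correlation of 0.57 at these times against a highest of 0.31 at the other times, which is consistent with a batch shared by the 9 arrays, such as cells plated or arrays run together. The labels name no batch, and no other biological explanation was tested. Within this batch each interferon has 1 array per time, so contrasts between interferons are balanced over it except for IFN-λ3 at 4 h.

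An array far from the others was untreated array d in the score of the immediate early genes, 0.592 above the mean of the other 3. Untreated array c lay 0.0638 above the others in the score of hypoxia and glycolysis genes. These were 2 of 21 list scores, and chance gives about 1 in 20. Immediate early genes rose from 0.5 to 1 h under all 5 interferons, by 0.428 with IFN-α, 0.579 with IFN-β, 0.314 with IFN-λ1, 0.305 with IFN-λ2 and 0.278 with IFN-λ3. Interferon signalling in proportion to the ISG response is left open: the rise with IFN-λ2 was 0.526 of that with IFN-β while the ISG score had a ratio of 0.0738, and the rise with IFN-λ2 lay 0.262 above the share that this ratio gives. Handling alike in all cultures as the only source is left open too, with an excess of 0.15 with IFN-β over the next largest rise. The values of 0.262 and 0.15 exceed the SD of a difference of rises between differently treated cultures (0.0625) but lie within the SD of 0.299 between the untreated arrays. To argue against either, the limit also asked for more than 2 times that SD of 0.299. No rise was that large, so these tests could not decide. The untreated arrays do not enter a rise from 0.5 to 1 h. No untreated arrays were taken at these times, so handling, signalling or both may be the source.

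Probes that name no single gene held a signal that no comparison used: 47 of 4646 changed with IFN-β (42 rose, 5 fell), against 19 with IFN-α, 7 with IFN-λ1, 4 with IFN-λ2 and 10 with IFN-λ3.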

How the results depend on the processing

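Background removal, leaving out the b arrays of 2 and 4 h, and the block for the ISG scores were tests chosen only after the results were seen. A count was taken as kept when it stayed within 1.5 times the reported one. The 5 ISG score differences kept direction and call under every alternative run. All 12 counts were kept without the dim filter, without the intensity trend, with the letter as a block, with the mean of probes and without the b arrays of 2 and 4 h, and the 5 counts against untreated with the 0.5 h baseline.

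With letter within time as a block, the counts became 2758 (IFN-β minus IFN-α), 123 (IFN-λ1 minus IFN-λ2), 176 (IFN-λ3 minus IFN-λ2), 130 (IFN-λ1 minus IFN-λ3), 1822 (persistence, type III minus type I) and 1107 (persistence, IFN-β minus IFN-α). With this block 5 lists gained a camera call and 0 results lost one: immediate early and heat shock genes for IFN-λ1 minus IFN-λ2 (adjusted p = 0.0113 and 0.0278), and immediate early genes, NF-kB targets and cholesterol genes for persistence of IFN-β minus IFN-α (0.0139, 0.0386 and 0.0265). With only the arrays compared, the persistence counts were 1267 and 682. The cause of these shifts was not tested. By adjusted p alone, which drops the fold limit, 2417, 5099, 931, 923 and 1022 genes changed with IFN-α, IFN-β, IFN-λ1, IFN-λ2 and IFN-λ3; with background removed, which enlarges changes of dim genes, 211, 492, 83, 50 and 95. A minimum difference of 0.5 left 119, 27, 43, 4 and 175 genes for IFN-β minus IFN-α, IFN-λ1 minus IFN-λ2, IFN-λ3 minus IFN-λ2, IFN-λ1 minus IFN-λ3 and type I minus type III, and 103 for persistence of type III minus type I. Over 4 to 12 h IFN-β minus IFN-α called 819 genes, and from 4 h the persistence of IFN-β minus IFN-α called 716; the cause was not tested.

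Reversed results were these. The immediate early genes as a list with IFN-λ2 and IFN-λ3 against untreated went to 0.0937 and 0.0847 with the letter as a block. Only untreated arrays have the letters c and d, so this block leaves arrays a and b as the untreated baseline. Array d, 0.592 above the mean of the others in the score of this list, then drops out. The list ranged over -0.0736 to 0.144 and -0.0725 to 0.131 when each array was left out. It was called at the low end without untreated array c and at the high end without d. The cause of the other reversals was not tested. APOB, type I minus type III, went to 0.00349 over 4 to 12 h. From 4 h, persistence of type III minus type I reversed for MLKL (-0.191) and HK2 (-0.144). It also reversed for the lists of antiviral ISGs (-0.0519), of chemokines and cytokines (-0.155) and of apoptosis (-0.00101). Persistence of IFN-β minus IFN-α from 4 h reversed for IFNLR1 (0.085) and SOCS1 (0.209).

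Leaving out each array in turn gave 135 to 149 genes for IFN-α, 306 to 322 for IFN-β, 47 to 62 for IFN-λ1, 22 to 32 for IFN-λ2 and 57 to 68 for IFN-λ3, and 1423 to 1578 (IFN-β minus IFN-α), 65 to 76, 94 to 106, 42 to 52 (type III pairs), 3495 to 3838 (type I minus type III), 476 to 703 and 306 to 373 (persistence); a group left with 1 array is assumed to vary like the others. The scores ranged over 0.675 to 0.693, 0.461 to 0.477, 0.692 to 0.702, -0.236 to -0.22 and 1.29 to 1.3. Of 502 named gene results, 60 lost their call without at least 1 array, and 39 counts per time moved and 169 were kept. Of 252 list results, 18 lost their call with an estimated correlation and 0 gained one. Not run were neqc and the other normalizations from raw signals, and the block for the bead chip, since the columns could not be assigned; no background correction with quantile normalization is what was reported. Signal over background limits the genes dark in untreated cells, whose folds were given as lower bounds where their differences were not.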

Other observations

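The regroupings and lists were fixed before the data were examined; all values on genes that differed in all 5 interferons at 0.5 h come from tests chosen only after the result was seen.

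At 0.5 h, 10 genes differed from untreated by at least 0.5 in all 5 interferons, most without passing in every interferon. The metallothioneins MT2A (mean log2 0.62), MT1X (0.769) and MT1E (0.854), which buffer zinc, and EGR1 (1.3) were higher, and SRXN1 (-0.908), TXNRD1 (-0.746), PTGR1 (-0.717), SPP1 (-0.732), BBOX1 (-0.655) and F2RL2 (-0.563) were lower. SRXN1 alone had an adjusted p under 0.05 with every interferon (0.03 at most), and the lowest adjusted p of SPP1, MT2A, F2RL2 and MT1X were 0.11, 0.089, 0.052 and 0.087. Without untreated array c only 2 of the 10 remained, and without a, b or d, 7, 10 and 10, so most of this rests on array c. With the letter as a block, IFN-λ2 changed 32 genes against 22 without it. This block leaves arrays a and b as the untreated baseline and also adjusts b against a. The part of each in the shift was not tested.

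The list score of the cell cycle genes at 24 h, over untreated, was -0.311 (SD 0.033) with IFN-β and 0.131 (SD 0.016), 0.143, 0.169 and 0.136 with IFN-α, IFN-λ1, IFN-λ2 and IFN-λ3. No test was made of these values, and the untreated arrays had an SD of 0.08. Cholesterol genes rose from 6 to 24 h: 3, 5, 3, 5 and 4 of 14 members were called with IFN-α, IFN-β, IFN-λ1, IFN-λ2 and IFN-λ3, and camera called the list with IFN-β, IFN-λ1, IFN-λ2 and IFN-λ3 (adjusted p = 0.0013, 0.00024, 8e-06 and 0.00012) and with IFN-α lost its call (adjusted p = 0.053 with an estimated correlation). Without untreated arrays of the same age, what the interferons share here cannot be given to them. The lower cell cycle score with IFN-β is a difference between interferons of the same age (13 of 25 genes lower than with IFN-α over 2 to 24 h, camera adjusted p = 4.6e-07) and needs no untreated array.

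Regroupings of the arrays were counted for each comparison, 100 each with the real one. Those against untreated mix treated and untreated arrays over all times, so they still hold effects of treatment and time. Their median was 41 genes for IFN-α and 105 for IFN-β. The share as large as the real count was under 0.05 for IFN-α against untreated (139 genes, highest other 95, 1 regrouping as large). So it was for IFN-β (310, highest other 271, 1), IFN-λ1 (47, highest other 44, 1) and IFN-λ3 (59, highest other 65, 2). For the count of IFN-λ2 it was not (22, highest other 29, 5 regroupings as large). It was under 0.05 for IFN-β minus IFN-α (1646, highest other 1312, 1) and IFN-λ3 minus IFN-λ2 (100, highest other 85, 1). The same held for IFN-λ1 minus IFN-λ3 (51, highest other 51, 2) and type I minus type III (3752, highest other 576, 1). These shares were not adjusted over the comparisons and do not exclude chance by themselves. For IFN-λ1 minus IFN-λ2 the share was not under 0.05 (75, highest other 1208, 5). The 4 other regroupings as large all put the b arrays of 2 and 4 h on 1 side, a structure of the arrays and not of the interferons; among the 49 regroupings that spread those arrays more evenly the highest count was 31, and with letter within time as a block the real count was 123.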
